A study of Mus musculus with 2 samples.

How the data were processed

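Gene expression was measured on 2 Affymetrix microarrays, one hybridised with RNA of cortical thymic epithelial cells (cTECs) of Aire transgenic mice (Tg) and one with RNA of the same cell type of control mice (non-Tg). The group of each array was taken from its genotype label. The source labels give cTECs from 7 Tg and 5 non-Tg, which was read here as the number of animals pooled for each array, and both groups were NOD mice at day 7. Each group had 1 array. There was therefore no replicate error, and no p-value was computed for the comparison. How the cells were isolated is not given in the sources used here.

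Per the labels' protocols, total RNA was prepared with a column kit, 400 pg of it was copied and amplified to cDNA with the Ovation One-Direct system, and 5.5 µg of cDNA was fragmented and end-labelled with biotin. The deposited values are on a log2 scale, with 1 value per probe set and array for 28856 probe sets. The scale was inferred from the range, 4.22 to 13.7 on the Tg array and 4.22 to 13.6 on the non-Tg array, since natural-log or base-10 values of this size would exceed what a scanner records. The authors' background correction, normalization, summarisation software and genome build are not given in the sources used here. The arrays had medians of 5.43 (Tg) and 5.45 (non-Tg) and upper quartiles of 6.57 and 6.55. The lowest value was 4.22 on both arrays, and with values bounded below in this way log2 ratios of dim genes are compressed towards 0. The table held 0 columns of other samples. No scanner files, scan dates or detection calls were used here, so batches could not be examined, and precision was limited by the number of arrays.

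Gene names came from the platform annotation in GEO. Of the probe sets, 21789 had 1 gene symbol, 1621 had several and 5446 had none here. The gene IDs of 21698 of the single-symbol probe sets were found in a RefSeq gene table of the GRCm38.p6 assembly, and 0 symbols differed from it. That table was used for names, biotypes and the order of neighbouring genes only, and no coordinates are given. Probe sets with several symbols were not used to name a gene. For each of the 19938 genes, the probe set with the highest mean value over both arrays was taken.

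The values were used as deposited. A floor was set at the 25th percentile of all values of both arrays, a log2 value of 4.80, and lower values were raised to it for the ratio. A gene passed the filter if its value reached the 50th percentile of all probe sets on at least 1 array (5.43 for Tg, 5.45 for non-Tg), which 11422 genes did. The log2 ratio was Tg minus non-Tg. A rule of size was used in place of a test: a gene was counted as higher or lower if it passed the filter and its ratio was at least 2-fold, a log2 ratio of 1. Where one of the values lay under the floor, the fold is given as a lower bound.

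Other sources of scale were available for a ratio without replicates. For the 658 genes with at least 2 probe sets past the filter, the log2 ratios of the 2 brightest were subtracted from each other. The SD of that difference, divided by the square root of 2 to estimate the error of 1 probe set, was 0.302. For single genes, the ratio was placed among those of the 500 genes closest in mean level. For gene lists, the median over the measured members was placed among the medians of 10000 random lists of the same size matched on mean level in 20 bins. These percentiles describe this pair of arrays and do not test the conditions.

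Before the data were examined, 28 gene lists were fixed from general knowledge: the transgene with the gene whose promoter drives it, markers of cortical and medullary thymic epithelial cells (TECs), antigen presentation, tissue-restricted genes, 6 other cell types, and general cell states. The rule for named genes was fixed too. It took Aire and Psmb11, the 10 genes with the highest and the 10 with the lowest ratio among genes past the filter, and of each list up to 4 members beyond 2-fold or, where there were none, the 2 with the highest mean level. Sex-linked genes were left out of the rule for single genes. Members named outside that rule were chosen after their values were seen.

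Scripts were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. The calls were tested on simulated data for the comparison of Tg with non-Tg. Normal noise with the robust spread of the observed ratios at each level was added to the mean levels of the 28856 probe sets. The 19938 genes were then formed as above. At each fold, 50 genes were changed, drawn from genes with 1 probe set and a mean log2 level of at least 6.5, so that the recovery holds for such genes and not for dimmer ones. The rule recovered 2 of 50 genes changed 1.5-fold, 46 of 50 changed 2.5-fold, and 50 of 50 at 4-fold and at 8-fold, and it called 7 unchanged genes. Noise of this form leaves out any wide tails of the observed ratios, so the 7 is no error rate for the calls on the real arrays. Alternatives fixed beforehand were 3 other scalings of the arrays, other floors and filters, other fold thresholds, and the mean over all probe sets of a gene. Leaving out probe sets by their suffix was not possible, because the probe set IDs of this array carry none.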

Results

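The 2 arrays addressed what cTECs express when they are made to produce Aire, the transcriptional regulator that medullary TECs use to transcribe genes of peripheral tissues. In the Tg mice, which are on the diabetes-prone NOD background, Aire was placed under the promoter of Psmb11, which encodes the thymoproteasome subunit β5t of cTECs. Per the labels, one array held cTEC RNA from 7 Tg and the other from 5 non-Tg, read here as pooled animals, at day 7. Values below are log2 levels as deposited, and each ratio is Tg over non-Tg. With 1 array per group, no difference has a replicate check. The closest available spread is an SD of 0.302 per probe set, estimated from the differences between log2 ratios of 2 probe sets of 1 gene. Probe sets of 1 gene read the same RNA on the same array. This SD therefore holds no variation between animals, pools or amplifications, and the error of a ratio can be larger.

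Aire was higher on the Tg array. Its level was 7.33 in Tg and 6.06 in non-Tg, a log2 ratio of 1.28 or 2.43-fold, which exceeded the ratios of all 500 genes closest to it in level (percentile 100, SD of those ratios 0.360). The gene has 1 probe set on this array, and whether that probe set lies wholly within the transgene is not stated. Psmb11, the source of the promoter, had levels of 10.51 in Tg and 10.15 in non-Tg, a log2 ratio of 0.37 (1.29-fold). This was the 95th percentile among its 500 level neighbours, whose ratios had an SD of 0.213, and it did not reach 2-fold. The median of both genes, 0.82, was at percentile 99.9 of level-matched random pairs. Since the pair includes Aire, that percentile mostly restates the Aire ratio and says nothing further about Psmb11.

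Genes that define cTECs had similar levels on both arrays. Of the 18 cortical genes, 18 were measured and 17 passed the filter, and 0 were 2-fold apart in either direction. The log2 ratio lay above 0 for 16 of them and below 0 for 2, with a range from -0.19 to 0.57. The chemokine gene Ccl25 differed by a log2 ratio of 0.06 and the keratin gene Krt8 by 0.05. Prss16, the thymus-specific serine protease, had a log2 ratio of 0.15, and the Notch ligand gene Dll4 0.25. The widest ratios in the list were 0.57 for the chemokine scavenger gene Ackr4 and 0.48 for the aminopeptidase gene Enpep, at percentiles 89.8 and 90.8 of their level neighbours. The list median of 0.08 was at percentile 75.3 of level-matched random lists.

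Markers of medullary TECs did not separate the arrays either. Of 20 measured genes, 14 passed the filter and 0 were 2-fold apart, with 10 ratios above 0 and 10 below. Krt5, a basal keratin, had a log2 ratio of 0.34, and Trp63, an epithelial transcription factor, -0.12. The ratio of Fezf2, the other known regulator of tissue-restricted genes in the medulla, was -0.08. The highest ratios were those of Ctss, a lysosomal protease, at 0.77, and of the costimulatory gene Cd86 at 0.72. The median was 0.00 to 2 decimals (percentile 57.7).

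**Figure D1:**
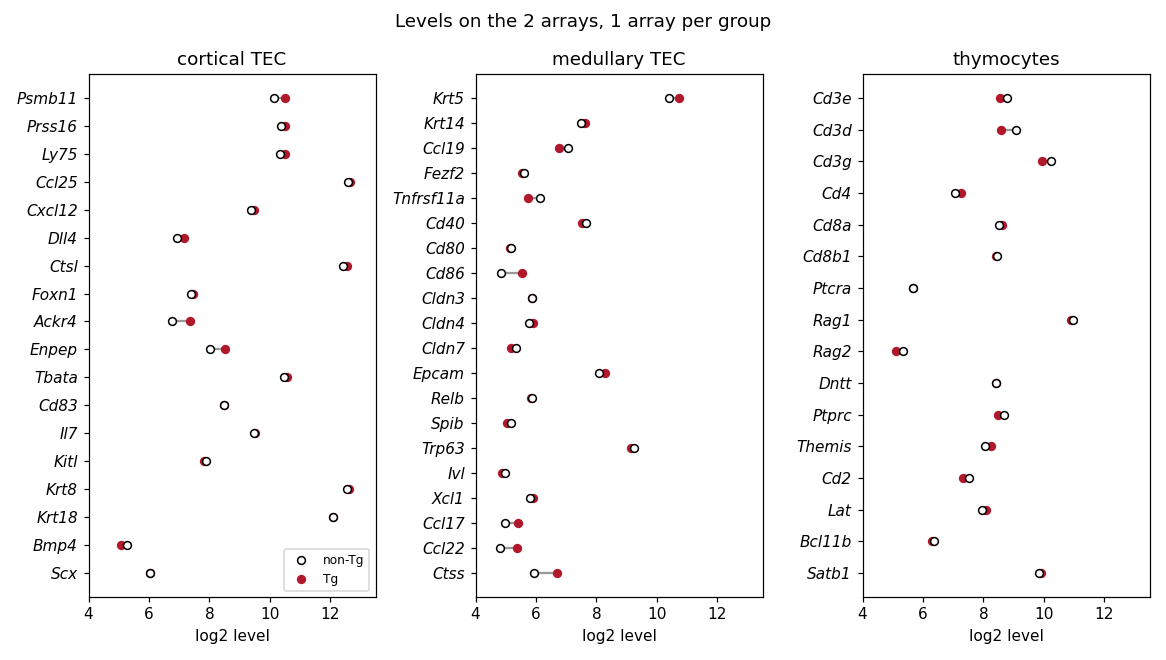
Log2 levels (x axis) of the measured genes of the cortical TEC, medullary TEC and thymocyte lists (y axis) on the Tg array (filled) and the non-Tg array (open), 1 array per group and no error bars. The points of most genes nearly coincide, and the widest gap, that of Ctss, is a log2 ratio of 0.77.

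The main question of such a design is whether tissue-restricted genes appear in the cortex. Among 142 distinct genes in 11 lists of such genes, 130 were measured, 39 passed the filter, 0 were 2-fold higher and 1 was 2-fold lower in Tg. Of the 39, 38 had log2 ratios within 0.5 of 0, and their median was 0.00. The lower gene was Tubb3, a neuronal tubulin, at 5.59 in Tg and 7.03 in non-Tg (log2 ratio -1.44, 2.71-fold lower). These counts hold for the listed genes only. Outside the lists, the olfactory receptor gene Olfr99 was 4.25-fold and the taste cell gene Gnat3 2.95-fold higher in Tg. The parathyroid hormone gene Pth was at least 3.60-fold lower. Some members past the filter lay close to it on both arrays, such as Apoa2 at 5.49 in Tg and 5.51 in non-Tg.

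Genes widely used as Aire-dependent antigens were mostly dim on both arrays. Of 19 measured members, 3 passed the filter, and 5 lay under the floor on both arrays. The ratios ranged from -0.18 to 0.21, with a median of 0 (percentile 56.4). Level-matched random lists had a median of 0 as well, because of the floor, so that this percentile mostly counts ties. Insulin 2 (Ins2) had 5.03 in Tg and 5.13 in non-Tg, and Fabp2, an intestinal fatty acid-binding protein, 4.48 and 4.49. Among members past the filter, Pcp4, a Purkinje cell gene, had a log2 ratio of 0.21 and Tff3, a goblet cell secretory peptide, 0.03. Genes used as Aire-independent antigens had 7 of 15 measured members past the filter, 0 of them 2-fold apart, and a range from -0.17 to 0.36 (median 0, percentile 61.6). Nol4 had a log2 ratio of 0.03 and the epidermal keratin Krt10 -0.07. The highest ratio was that of the monoamine oxidase gene Maoa.

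Lists ordered by tissue gave similar values. Liver genes had 3 of 16 measured members past the filter and a median of -0.03 (percentile 17.8), with Trf (transferrin) at -0.32 and Apoa2 at -0.02. Pancreas genes had 3 of 14 past the filter and a median of 0 (percentile 58.7), with Ppy (pancreatic polypeptide) at -0.06 and Cela2a (an elastase) at 0.00. Intestine genes had 5 of 13 past the filter and a median of 0 (percentile 60.4), with the transcription factor Cdx1 at 0.01. Skeletal muscle genes had 9 of 16 past the filter and a median of -0.02 (percentile 34.1), with Actn3 at 0.35 and Acta1 at 0.00.

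Keratinocyte genes had 3 of 11 measured members past the filter and a median of 0 (percentile 66.0), with Sprr1b, a cornified envelope gene, at 0.14. Salivary, lacrimal and milk genes had 1 of 12 past the filter and a median of 0 (percentile 50), with the milk protein Wap at -0.14 and Dcpp1 at -0.18. Testis genes had 4 of 12 past the filter and a median of 0 (percentile 64.3), with the protamine Prm1 at -0.15 and Tnp2 at -0.13. Retina and lens genes had 2 of 10 past the filter and a median of 0 (percentile 60.5), with the lens crystallins Cryab and Cryaa at 0.29 and 0.28. Neural genes had 4 of 12 past the filter and a median of -0.07 (percentile 14), Tubb3 among them. In these dim lists the limit is the lower bound of the values: a change in transcripts that stay near background was not detectable. Where the median of such a list was 0, that of its random lists was 0 too. Ties from the floor then draw the percentile towards 50, and for the salivary, lacrimal and milk list they fix it there.

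**Figure D2:**
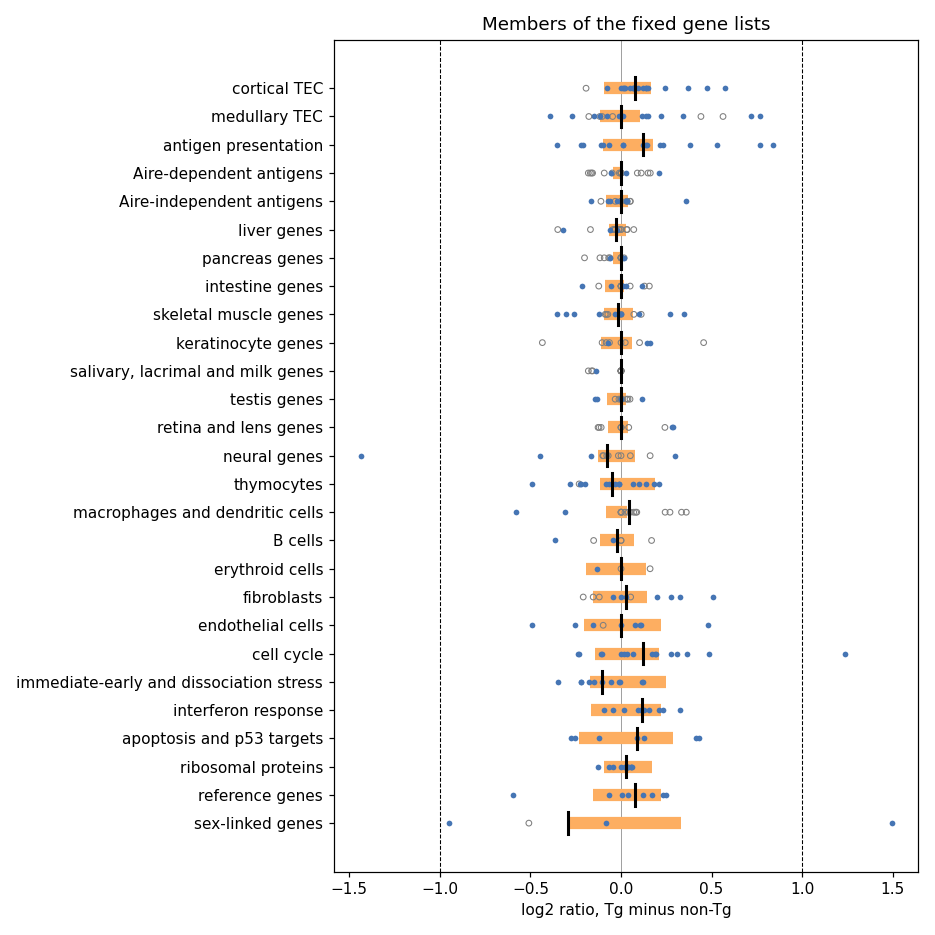
Log2 ratio of Tg over non-Tg (x axis) of each measured member of the fixed gene lists (y axis). Filled points passed the filter and open points did not, black bars are list medians, orange bars span the central 95% of the medians of 10000 level-matched random lists, and dashed lines mark 2-fold. The list of Aire and Psmb11 is not drawn, and Tubb3, Aurka and Xist lie beyond 2-fold.

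Genes of antigen presentation had 18 measured members, of which 18 passed the filter and 0 were 2-fold apart. The median was 0.12 (percentile 90.4), with 12 ratios above 0 and 6 below. The abundant members lay close together: B2m had a log2 ratio of 0.01 and Ctsl, the protease of the cortical class II pathway, 0.14. The peptide transporter gene Tap1 had the highest ratio, 0.84 (1.79-fold, percentile 98.0 of its level neighbours), and the class I regulator Nlrc5 had 0.53. The lowest was the proteasome activator gene Psme1 at -0.35.

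RNA of thymocytes was present on both arrays at similar levels. Of 16 measured thymocyte genes, 15 passed the filter and 0 were 2-fold apart. The recombinase gene Rag1 had 10.89 in Tg and 10.96 in non-Tg, and the T cell receptor component gene Cd3g 9.94 and 10.23. Ratios ranged from -0.49 for Cd3d to 0.21, with a median of -0.05 (percentile 12.7). Macrophage and dendritic cell genes had 2 of 16 members past the filter, Tyrobp at -0.58 and C1qa at -0.31, while the list median over all 16, most of them dim, was 0.05 (percentile 98.7). The median and the filtered members of this list thus differed in sign. B cell genes (median -0.02, percentile 30.2, with Ebf1 at -0.36 and Pax5 at -0.04), erythroid genes (median 0 over 3 measured genes, percentile 57.7, with Slc4a1 at -0.13 and Alas2 at 0.16), fibroblast genes (median 0.03, percentile 72.5, with Postn at 0.51 and Dcn at 0.28) and endothelial genes (median 0, percentile 51.4, with Pecam1 at 0.48 and Cdh5 at -0.16) held no member beyond 2-fold. Across these 6 cell types, 35 of 61 measured genes passed the filter.

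Among cell states, the mitotic kinase gene Aurka was higher in Tg, at 7.23 against 5.99 (log2 ratio 1.24, 2.36-fold). It was the only one of 16 measured cell cycle genes beyond 2-fold. The proliferation markers Mki67 and Top2a had ratios of -0.11 and 0.01, and the list median was 0.12 (percentile 84.7). Immediate-early and dissociation stress genes had a median of -0.11 (percentile 8.68), with 9 of 11 ratios below 0, among them Jun at -0.06 and Atf3 at -0.22. Interferon response genes had a median of 0.12 (percentile 84.3), with Cxcl10 at -0.10 and Oasl2 at 0.11. Apoptosis and p53 target genes had a median of 0.09 (percentile 68.7), with Trp53inp1 at 0.41 and Ccng1 at 0.09. Ribosomal protein genes had a median of 0.03 (percentile 45.3), with Rps6 at 0.04 and Rps14 at 0.03. Reference genes had a median of 0.08 (percentile 69.8). Actb was at 0.04 and Ywhaz at 0.17, and the general transcription factor gene Tbp was at -0.60.

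Of the 4 measured sex-linked genes, 1 was beyond 2-fold. Xist, the RNA that silences the X chromosome in females, was 2.82-fold higher on the Tg array, at 7.78 against 6.28, the highest value among its 500 level neighbours (percentile 100). The Y-linked Eif2s3y was lower in Tg, at 6.40 against 7.36 (log2 ratio -0.95, 1.93-fold). The Y-linked Kdm5d had -0.08, and Uty, which did not pass the filter, had 4.94 in Tg and 5.45 in non-Tg. The median of the 4 measured genes was -0.30 (percentile 2.41).

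Over all genes, the arrays were alike. Of 11422 genes past the filter, 91 were 2-fold or more higher and 43 were 2-fold or more lower in Tg, 1.17% together. The values of the 28856 probe sets correlated across probe sets with a Pearson r of 0.986, where probe sets are not independent replicates. The SD of the log2 ratio over genes past the filter was 0.331, and the median ratio was 0.01. Across the 658 genes with at least 2 probe sets past the filter, the ratios of 2 probe sets of a gene correlated with a Pearson r of 0.387 and a Spearman coefficient of 0.404, where genes are not independent replicates. Protein-coding genes made up 84 of the 91 and 36 of the 43.

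The olfactory receptor gene Olfr99 was 4.25-fold higher (7.58 against 5.49), and Brms1l, a component of histone deacetylase complexes, 4.03-fold (7.41 against 5.40). The zinc finger gene Zfp626 was at least 3.82-fold higher, since its non-Tg value lay under the floor. The aldehyde dehydrogenase gene Aldh3b3 was 3.49-fold higher, the sorting nexin gene Snx11 3.46-fold and Cyb5d1 3.35-fold. Syde2 was 3.01-fold higher. Gnat3, the taste and tuft cell G protein gustducin, was 2.95-fold higher, the transporter gene Slc49a4 2.93-fold, and the tight junction gene Cldn1 2.87-fold. On probe set choice, Aldh3b3 fell under 2-fold when its 3 probe sets were averaged (log2 ratio 0.71), while the second probe set of Cyb5d1 gave 1.63, at levels within 0.3 of the first on both arrays.

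Among the genes lowest in Tg were genes annotated as small RNAs, the microRNA gene Mir103-2 at least 4.09-fold and the small nucleolar RNA gene Snord61 4.06-fold lower. Each had 1 probe set, and whether its signal came from the small RNA or from a longer transcript was not tested. Parathyroid hormone (Pth) was at least 3.60-fold lower, at 4.59 in Tg and 6.65 in non-Tg. Nynrin was 3.48-fold lower and the zinc finger gene Zfp558 2.86-fold. Gch1, the first enzyme of tetrahydrobiopterin synthesis, was 2.84-fold lower, Cfap57, a cilium gene, 2.81-fold, Wdr5, a subunit of histone methyltransferase complexes, 2.81-fold, the N-terminal acetyltransferase gene Naa20 2.75-fold, and Tubb3 2.71-fold. Averaged over their probe sets, Nynrin, Cfap57 and Zfp558 had log2 ratios of -0.53, -0.81 and -0.73 and no longer reached 2-fold, while the second probe set of Naa20 gave -1.45, again at levels within 0.3 of the first.

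**Figure D3:**
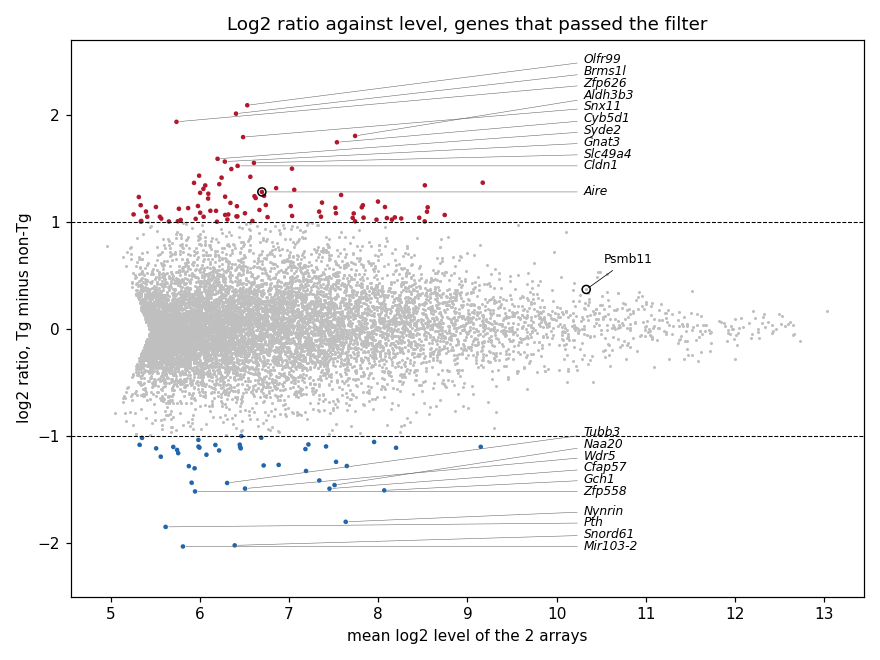
Log2 ratio of Tg over non-Tg (y axis) against the mean log2 level of the 2 arrays (x axis) for the 11422 genes past the filter, 1 array per group. Dashed lines mark 2-fold, with 91 genes above (red) and 43 below (blue), labels name the 10 highest and 10 lowest genes that are not sex-linked, and circles mark Aire at 1.28 and Psmb11 at 0.37.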

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

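The tests weighed here for the T cell receptor segments and for female RNA in the pools were chosen after those values had been seen; those of the genes beyond 2-fold were written down before their results. Probe sets without a gene name of their own, which entered no comparison above, held 29 that were 2-fold or more higher and 21 that were 2-fold or more lower in Tg among 2755 past the filter. That is 1.81%, against 1.17% of named genes. Their log2 ratios reached 2.34 and -2.70.

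The first pattern is the named genes beyond 2-fold. For 21 of these 134 genes another probe set passed the filter. Its log2 ratio in the direction of the call had a median of 0.32 (95% bootstrap interval 0.08 to 0.62), so error of single probe sets may account for part of the calls. In 6 of the 21 genes the other probe sets averaged 2-fold too. Each of the 6 had one whose levels lay within 0.3 of the first on both arrays, which could be the same sequence read again. In the other 15, a split made after the values were seen, the median was 0.14 (0.06 to 0.35). That split leaves out the highest ratios, so a median under 0.32 follows from the split itself. Chance loss or gain of scarce transcripts in amplification from 400 pg cannot be told apart either. The share of genes beyond 2-fold was 1.02 times as high in the 2856 brightest genes as in the rest. That share does not argue against such loss, because the brightest genes had mean levels from 7.42 to 13.0 and ratios narrowed within that range. The SD of the 500 level neighbours was 0.338 for Actn3 (8.22 in Tg) and 0.193 for Actb (12.4 in Tg). Ratios of dim genes are compressed as well: the SD was 0.293 in the 2856 dimmest genes. It reached 0.370 at higher levels and was 0.317 in the 2856 brightest. A response to Aire stays open and untested, since each genotype has 1 array.

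The second pattern is in T cell receptor gene segments, where 2 of 34 probe sets past the filter were 2-fold or more higher in Tg and 3 were 2-fold or more lower. The 2 higher ones were annotated to several gamma chain V segments, with log2 ratios of at least 2.19 (4.58-fold) and at least 1.27, since both non-Tg values lay under the floor. The lowest, at least 3.22-fold lower, was annotated to 2 alpha chain V segments, but the 7 other probe sets with that annotation lay between 0.05 and 0.48. A 2-fold difference in thymocytes as a whole between the pools is argued against by the thymocyte list. Its median log2 ratio was -0.052 and 0 members were 2-fold apart. With 5 ratios above 0 and 11 below, a smaller difference stays open. Among the segments, 7 annotations lay above 0 and 8 below, which restates that they were picked for standing at both ends. The thymocyte list holds no gamma chain gene, so it cannot show whether cells with a gamma chain receptor alone differed between the pools. Few thymocyte clones sampled per pool could give such values and stay open, as do error of single probe sets, cross-hybridisation and a different repertoire in Tg mice: the SD over 15 annotations was 0.79, against an upper end of 0.58 for the central 95% of level-matched random sets, but the segments were examined because some were extreme, so that this SD restates the pattern.

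The third pattern is Xist 2.82-fold higher and Eif2s3y 1.93-fold lower in Tg, which may reflect more female RNA in the Tg pool. The 3 Y-linked genes past the filter had a median log2 ratio of -0.081, with all 3 below 0, the others being Kdm5d at -0.08 and Sry at -0.03. These are too few to decide, and sex and genotype cannot be told apart for genes that differ between the sexes.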

How the results depend on the processing

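No paired analysis was possible because each group has 1 array, and no replicate could be left out. The counts of genes 2-fold higher and lower stayed within 1.5 times the reported 91 and 43 under every scaling, floor, filter and probe set rule tried, between 72 and 98 higher and between 32 and 47 lower, and for protein-coding genes only, an alternative chosen after seeing the data (84 and 36). Quantile normalization shared 80 and 43 of the reported genes, and averaging probe sets 77 and 37. At 1.5-fold the counts were 541 and 357, and at 3-fold 7 and 4. Leaving the filter out changed no count, because the floor already removes such genes. The Aire log2 ratio ranged from 1.25 to 1.30 and that of Psmb11 from 0.35 to 0.39. List medians moved by more than 1 SD of random lists in the cases that follow, where the filter at the 75th percentile leaves fewer members by construction and the floor sets values near it to 0. With that filter the medians were 0.14 (medullary TEC), -0.32 (liver), 0.35 (muscle), 0.29 (retina and lens), -0.94 (neural), 0.39 (fibroblasts), 0.16 (endothelial), 0.25 (apoptosis), -0.58 (macrophages and dendritic cells) and 0.27 (sex-linked). Those of medullary TEC, muscle, macrophages and dendritic cells, and sex-linked genes thereby turned sign. The values for liver (Trf), muscle (Actn3), retina and lens (Cryab), and macrophages and dendritic cells (Tyrobp) were each that of the named gene alone. Neural (Nefm, Tubb3), fibroblast (Dcn, Postn), endothelial (Pecam1, Cdh5) and sex-linked (Xist, Eif2s3y) values rested on the named genes only. They describe those genes and not the lists. That filter left no member, and so no value, for the Aire-dependent, Aire-independent, pancreas, intestine, keratinocyte, salivary, testis, B cell and erythroid lists. With no floor they were -0.014 (Aire-dependent), 0.030 (Aire-independent), -0.061 (pancreas), -0.045 (retina and lens), -0.12 (B cells) and -0.10 (erythroid), and the salivary, lacrimal and milk list, whose random lists had an SD of 0, went to -0.0054. With the floor at the 50th percentile they were 0 (liver, neural, macrophages and dendritic cells) and -0.045 (sex-linked), and with loess -0.0041 (liver). Of 22 named genes beyond 2-fold, 18 were so under every scaling, floor and probe set rule, and the other 4 (Aldh3b3, Nynrin, Cfap57, Zfp558) lost it only when probe sets were averaged. The cause was not tested. Folds given as lower bounds depend on the floor: with the floor at the 50th percentile the log2 ratios shrank to -1.39 for Mir103-2, -1.20 for Pth and 1.29 for Zfp626. Signal close to the lower bound limits all dim genes.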

Other observations

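The tests on interferon-gamma, parathyroid, tuft cell and neighbouring genes were written down before their results were seen; those on zinc finger genes and on lower genes alone around Psmb11 were chosen after. Of 230 zinc finger genes with a Zfp symbol past the filter, 11 were beyond 2-fold, 9 higher and 2 lower, where level-matched draws gave a median of 3 and an upper end of the central 95% of 6. The family was picked because it recurred among those genes, so that the count describes these arrays and does not test the family. Zfp626, Zfp882, Zfp949 and Zfp664 were among the higher ones and Zfp558 and Zfp141 among the lower. Members of this family share similar sequences, so that cross-hybridisation is a possible explanation beside a change in the genes; it was not tested. Of 1027 measured olfactory receptor genes, another large family, 32 passed the filter, with 1 higher (Olfr99) and 1 lower (Olfr920). On these few genes that share was also above the 1.17% of all genes past the filter. No level-matched draws were made for this family, so it gives no contrast to the zinc finger genes.

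Tap1, Ctss, Nlrc5, Cd86 and Ciita, all of antigen presentation or costimulation, had log2 ratios of 0.84, 0.77, 0.53, 0.72 and 0.38. They were picked for their ratios, and the non-Tg value of Cd86, 4.83, lay just above the floor of 4.80. Of the 18 measured antigen presentation genes, 12 lay above 0 and 6 below. Among the lower ones were Psme1 at -0.35, Psme2 at -0.22, Tapbp at -0.21, H2-DMa at -0.11 and H2-Eb1 at -0.10. The costimulatory gene Cd40 was at -0.15, and Cd80, which did not pass the filter, at -0.05. An interferon-gamma response was considered as a possible explanation. The 12 other interferon-gamma induced genes past the filter had a median of 0.036 (range -0.28 to 0.76, the highest being Gbp7), which argues against a response that raises these genes together by the size seen in the first group. That size comes from genes picked for high ratios, and a smaller response stays open.

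Single genes that mark rare cell types stood among the extremes. Lower Pth could come from fewer parathyroid cells, which can lie next to or within the thymus. The 3 other parathyroid genes past the filter (Chga, Gata3, Tbx1) had a median of -0.27, too few and too dim to decide. Casr, which did not pass, had a log2 ratio of 0.02. For Gnat3, with a log2 ratio of 1.56, more tuft cells in the Tg pool stay open. The 6 other tuft cell genes past the filter had a median of -0.12 (SD 0.408, range -0.92 for Alox5ap to 0.23 for Pou2f3). Of those that did not pass, Dclk1 (0.33) and Trpm5 (0.20) were higher in Tg, and Chat (-0.04) and Il25 (-0.10) lower. Most of these genes lay near the floor on both arrays, so they do not decide it.

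Nynrin and Gch1, both among the 10 lowest, lie on the chromosome of Psmb11, separated from it by 33 and 45 measured genes. Among the 100 measured genes nearest to Psmb11, these 2 were the genes beyond 2-fold, where stretches of 100 genes gave a median of 1 and an upper end of the central 95% of 4; 6.6% of stretches held 2 or more lower genes. DNA of another strain carried along with a construct at that locus could lower the signal of single probe sets (the other 2 of Nynrin gave -0.27 and 0.48), but the count does not decide it, and the site of the construct is not stated in the labels. Aire is known to act on neighbouring genes together; 2 adjacent pairs occurred among the genes beyond 2-fold, against a median of 1 and an upper end of 4 in level-matched draws, and in 1 of the 2 pairs the genes moved in opposite directions.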
